A study of Anser cygnoides with 4 samples.

How the data were processed

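Thymic cells of Zhedong White geese, all female, were profiled with a droplet 3' single-cell assay (10x Genomics Chromium, version 3 chemistry) and sequenced on an Illumina NovaSeq instrument. There were 4 libraries, 1 for each of the stages E25, D14, D70 and D200, and each pooled the cells of 3 geese. Each library came as a sparse matrix with its lists of features and barcodes. The deposited values are raw counts, whole numbers of UMIs per gene and barcode, made by the authors with Cell Ranger. The authors' processing notes give version 7.1.0 and the headers of the count files give version 8.0.0, and which of them made the matrices could not be settled. The genome build and annotation behind the counts are not given in the sources used here. No barcode had fewer than 500 UMIs in any library, so droplets below that number are missing. Whether some deposited barcodes are empty droplets was not tested, and free RNA could not be measured directly.

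The files list 22932 features, of which 9936 are named by a locus identifier. A reference gene table of a goose assembly gave a symbol for 738 of these by the same gene number. Of them, 700 were renamed and 38 were left because the symbol was already in use or shared. The table served for names and neighbouring genes only. Several textbook markers, such as the constant regions of the T cell receptor and FOXP3, have no named feature in the files, so no statement is made about them.

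Barcodes with at least 500 genes and at most 15% of UMIs from mitochondrial genes were kept. This left out 70, 234, 112 and 618 barcodes (E25, D14, D70 and D200) by genes and 4, 6, 5 and 7 by mitochondrial share. Doublets were scored per library with Scrublet in Scanpy 1.11.5. Its own threshold marked 0.0252% of D14 barcodes, which means that it did not work there. As fixed before the data were examined, the barcodes with the highest scores were instead left out at 0.8% per 1000 barcodes, 727, 1116, 673 and 945 of those otherwise kept. Of 41579 barcodes, 37062 cells were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components of scaled values, a shared-neighbour graph of 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0 gave 36 clusters. Stage and library are the same thing in this design, so no batch correction was made, and a cluster drawn mostly from 1 library may be that library.

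Cell classes were named from marker lists fixed before the data were examined. A marker counted in a cluster when at least 10% of its cells had a UMI and its CPM was at least 1.5-fold that of all other cells. A cluster took the name of the class with the largest share of counted markers, if these were at least 3 and at least 50% of the class's markers in the files. A cluster that passed this for more than 1 of the epithelial, fibroblast, endothelial and mural classes, as cluster 31 did, stayed unnamed. This 50% threshold, and the 100 CPM added to both sides before ranking leading genes, were set after the clusters were seen. The added 100 CPM decides whether cluster 4 passes the check on its 10 leading genes. Of the 36 clusters, 23 were named and 13 were not. The largest unnamed clusters held, from E25 to D200, 1.96%, 7.85%, 7.35% and 7.57% (cluster 2, led by HIVEP3, TNFRSF9 and CD5), 0.194%, 9.57%, 2.91% and 6.00% (cluster 3, SOX13, ITM2A and GATA3) and 0.0457%, 3.80%, 6.57% and 8.30% (cluster 5, CDK14, PTH1R and CD6). Further ones held 1.58%, 2.66%, 7.99% and 4.83% (cluster 6, RHEX and BLK), 0.160%, 3.06%, 6.48% and 4.11% (cluster 8, GPR82 and GPR55), 3.12%, 3.49%, 3.02% and 2.43% (cluster 10, SNTB1, CDK6 and DNTT) and 0.0914%, 1.13%, 1.32% and 6.24% (cluster 16, RSAD2 and RNF213). Clusters 12, 13 and 23 held 10.6%, 9.43% and 5.41% of cells at E25 and at most 0.286% at any later stage. Their leading genes included HIVEP3, CD3D and CD5 (cluster 12), SOX13, ITM2A and GATA3 (cluster 13) and RRM2 and PCNA (cluster 23). Cluster 13 shares the leading genes named for cluster 3, so whether both are the same population split by library cannot be told. The remaining unnamed clusters were cluster 24 (0.560%, 1.20%, 1.37% and 1.46%), cluster 31 (0.400%, 0.275%, 0.452% and 0.0961%, with both fibroblast and epithelial markers) and cluster 35 (0.0228%, 0.0664%, 0.226% and 0.0641%, IL1RL1, HDC and GATA2).

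Shares are percentages of kept cells with exact Clopper-Pearson 95% intervals. Where a count was 0, the limit is 3 counts of the total. For ratios, raw counts were summed over the kept cells of a library, or over the cells of a class with at least 200 cells in both libraries, and scaled to CPM, with the summed total as denominator. Ratios of sums carry an exact conditional 95% interval, and list members are log2 ratios after adding 1 CPM to both sides. All intervals cover counting error only. The 3 comparisons are between adjacent stages. As each stage had 1 library, no test was made and no p-value or count of changed genes was computed. Depth was compared only after thinning each cell to 1000 UMIs, with at least 2 UMIs of the G2 and M list counted.

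Genes were named by a rule fixed before the data were examined. It takes the 6 highest and 6 lowest log2 ratios over all cells among symbols with at least 50 CPM in either library, the 5 highest and 5 lowest within the double-positive-like class, and up to 4 members with the largest ratio of each list described. It covers members with at least 20 CPM in either library. Of 34 gene lists fixed beforehand, each was summarised by its median log2 ratio, by its members at least 1.5-fold higher or lower, and by the percentile of its median among 10000 random lists matched in 20 expression bins. SMC4 is named outside this rule, after its values were seen, as are the genes followed across classes in the closing section. Leading genes and markers of clusters are named as identity only. Some genes that the rule selects are withheld for evaluation and left out of the text.

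The procedure was tested on Poisson counts drawn from the mean profile of each pair of libraries, at their totals, with known folds of 1.5, 2 and 4 set in 200 genes. Over 6513, 6562 and 6641 genes (D14 over E25, D70 over D14, D200 over D70), at least 98.6%, 98.4% and 98.2% of the genes with a set fold came back within 1.2-fold. The intervals covered 95.1%, 95.6% and 95.1% of unchanged genes, and 90.1% to 97.0% of the genes with a set fold. The draws follow the Poisson model that the intervals assume, so this checks the calculation only. Spread between cells, geese or libraries was not simulated. Of 200 lists with no set fold per comparison, 4.5%, 4% and 6% had a median outside the central 95% of random lists. The alternatives fixed beforehand varied the gene minimum (300 and 800), the mitochondrial limit, doublet removal, the resolution (0.5 and 1.5), the variable genes (3000), centring on each library, the scaling (edgeR 4.0.16, DESeq2 1.42.0, mitochondrial and ribosomal genes left out, mean over cells), the pseudocount (5 CPM), the list floor (50 CPM and none) and the thinning (2000 UMIs, none, 1 UMI). Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Matplotlib 3.10.9 and R 4.3.3 were used.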

Results

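Gene expression in single thymus cells of female Zhedong White geese, a domestic breed, was measured at 4 stages: embryonic day 25 (E25) and days 14, 70 and 200 after hatching (D14, D70 and D200). Each stage had 1 droplet library, made from the pooled thymic cells of 3 geese. The files held 9558 barcodes with 50293632 UMIs at E25, 11896 with 42717147 at D14, 9189 with 29645053 at D70 and 10936 with 24559922 at D200. After filtering, 8757, 10540, 8399 and 9366 cells were kept, with medians of 3191, 2329, 2344 and 1592 UMIs per cell. With 1 library per stage there was no replicate check, so no difference between stages could be tested, and a difference between stages cannot be told apart from a difference between libraries. Values below are therefore given as levels in both libraries or as their ratio, and every interval (95%) covers counting error only. Genes are named by the symbols of the files or of a matching reference table, and the files hold no gene positions.

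Which cells made up the thymus at each stage was described by class, each named "-like" from marker genes. Double-positive-like cells, which carried RAG1, RAG2, DNTT, CD4 and CD8A, the genes of T cell receptor rearrangement and of both co-receptors, held the most cells at every stage among the named classes. They made up 48.0% of kept cells at E25 (Clopper-Pearson interval 46.9% to 49.0%), 37.4% at D14 (36.4% to 38.3%), 28.0% at D70 (27.0% to 29.0%) and 38.4% at D200 (37.4% to 39.4%). Mature single-positive-like T cells, marked by the egress and survival genes KLF2, S1PR1, CCR7 and IL7R, numbered 1 cell at E25 (0.0114%). They held 0.968% of cells at D14 (0.790% to 1.17%), 9.97% at D70 (9.33% to 10.6%) and 3.07% at D200 (2.73% to 3.44%). These shares depended on the settings and were up to 0.411% at E25, 2.97% at D14 and 17.6% at D70 (all at resolution 0.5) and 8.74% at D200 (at least 800 genes). They leave out the unnamed cluster 12, which held 10.6% of cells at E25 and 0.133% at D14. It carried CCR7, IL7R and CD40LG, 3 of the 14 markers of this class, without reaching the naming rule, so the low share at E25 depends on the naming. Regulatory T-like cells, marked by IL2RA and CTLA4, held 0.274%, 1.46%, 5.91% and 2.07%. Over the settings they ranged up to 1.98% at E25 and 3.28% at D14 (both at resolution 1.5), from 1.38% to 7.68% at D70 and from 1.43% to 3.85% at D200. Cycling-like cells held 16.3% at E25 (15.5% to 17.1%), 21.7% at D14 (21.0% to 22.5%), 6.19% at D70 (5.69% to 6.73%) and 7.30% at D200 (6.78% to 7.85%). The unnamed cluster 23 had RRM2 and PCNA among its leading genes, like the cycling-like cluster 11, without reaching the naming rule. It held 5.41% of cells at E25 and 0 cells at D14, so the difference between E25 and D14 depends on this naming.

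B-like cells, marked by the transcription factors PAX5 and EBF1, held 0.285% of cells at E25 (0.185% to 0.421%), 2.66% at D14 (2.36% to 2.98%), 9.91% at D70 (9.28% to 10.6%) and 6.27% at D200 (5.78% to 6.78%). Plasma-like cells were 0 of 8757 at E25, which allows a share of up to 0.0343%, and held 0.256%, 0.333% and 0.320% after hatching. Dendritic-like cells held 0.240%, 0.835%, 0.750% and 0.534%, macrophage-like cells 0.525%, 0.607%, 0.381% and 0.491%. Granulocyte-like cells held 0.457%, 0.436%, 0.405% and 0.224%, and erythroid-like cells 0.377%, 0.190%, 0.0238% and 0.0961%, after a lysis of red blood cells during preparation. Clusters that met no marker rule stayed unnamed and held 33.6%, 33.5%, 38.1% and 41.2% of cells.

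Different clusters held most of the double-positive-like class at different stages, which bears on every value given within it. At E25 these were cluster 1 (31.9% of the library's cells, with NRXN3 among its leading genes) and cluster 7 (15.7%), at D14 cluster 0 (35.3%), at D70 cluster 4 (17.8%, in which ID3 and TNFAIP3 also lead) and cluster 0 (10.1%), and at D200 cluster 0 (34.4%). Clusters 1 and 7 took 99.6% and 99.7% of their cells from E25, so cell type and library cannot be told apart there. Cluster 4 took 81.9% of its cells from D70, so the same limit holds in large part at D70. Double-positive-like cells had low depth, with medians of 1993.5, 1184, 1248 and 1021 UMIs, near the filter of 500 genes. With a minimum of 800 genes, their share was 46.4%, 22.6%, 16.8% and 16.4% from E25 to D200. The differences between adjacent stages were then -23.8, -5.75 and -0.437 percentage points instead of -10.6, -9.35 and 10.4, so no order of D70 and D200 is read from this share. The difference of the cycling-like share between D14 and E25 and those of the regulatory T-like share likewise had the other sign in coarser clusters (resolution 0.5), at -0.833, -1.41 (D70 minus D14) and 0.0496 points (D200 minus D70).

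**Figure D1:**
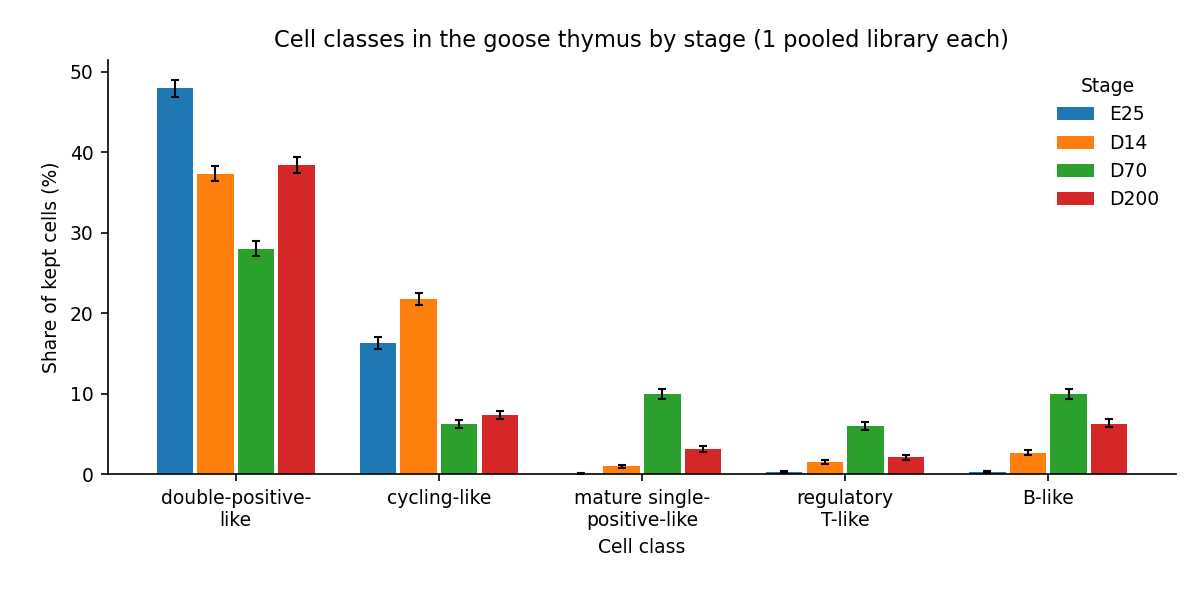
Share of kept cells (%) in 5 cell classes, with 1 bar per stage (1 pooled library of 3 geese each) and exact 95% binomial intervals for counting error. Double-positive-like cells held 48.0%, 37.4%, 28.0% and 38.4% of cells from E25 to D200, and cycling-like cells 21.7% at D14 and 6.19% at D70.

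The comparison of D14 with E25 asks how the thymus in the early weeks after hatching differed from the embryonic organ. Over all kept cells, heat shock and immediate early genes were higher at D14, B lineage, antigen presentation and T cell egress genes were higher too, and most measured extracellular matrix genes were lower. Of 13 measured heat shock and chaperone genes, 11 were at least 1.5-fold higher and 0 lower. The cytosolic chaperones HSP90AA1 (758 to 4445 CPM) and HSPA8 (387 to 1925 CPM) were 5.86-fold (5.80 to 5.93) and 4.97-fold (4.89 to 5.05) higher. HSPA2, of the same chaperone family as HSPA8, was 28.5-fold higher (27.3 to 29.7, 53.0 to 1510 CPM), and HSPH1, a co-chaperone, 5.24-fold (4.91 to 5.61, 24.5 to 129 CPM). Of 11 immediate early and dissociation stress genes, 8 were higher and 0 lower, among them the phosphatase DUSP1 (84.9 to 495 CPM) and the transcription factor genes FOSB (13.6 to 54.3 CPM) and JUN (175 to 577 CPM). The medians of both lists, 1.23 and 1.52 (log2), lay at percentile 100 of 10000 random lists matched for expression, a description of these libraries and not a test. The labels give the same handling for every library, storage in a tissue solution and dissociation at 37 °C for 20 min, but no storage times.

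Of 14 maturation and egress genes, 9 were higher and 0 lower at D14 (median 0.74, percentile 100). KLF2, which drives the genes of thymic egress, went from 11.0 to 98.9 CPM, a 9.02-fold difference (8.21 to 9.94). STAT4, a cytokine signalling factor, was at 25.6 and 130 CPM, KLF6 at 16.5 and 70.8 CPM, and FOXO1 at 98.9 and 245 CPM. All 8 measured antigen presentation genes were higher (median 1.09, percentile 99.99), with B2M, the light chain of MHC class I, at 118 and 399 CPM. Of 5 B cell genes, 4 were higher (median 1.94, percentile 99.99), such as PAX5 (3.03 to 20.6 CPM) and EBF1 (14.2 to 57.1 CPM), as the share of B-like cells went from 0.285% to 2.66%. IGLL1, a name that avian annotations give to the immunoglobulin lambda light chain, was 30.7-fold higher (29.5 to 32.0, 58.1 to 1785 CPM). JCHAIN, the joining chain of secreted antibodies, was 30.4-fold higher (26.7 to 34.8, 5.26 to 160 CPM), and MZB1, a chaperone of antibody secretion, 25.4-fold (21.4 to 30.4, 3.12 to 79.4 CPM). The 27 plasma-like cells of D14 held 85.0% of that library's IGLL1 UMIs. PPP1R36, a phosphatase subunit gene that lies directly beside HSPA2 in the reference table with 0 genes between, was 18.8-fold higher (16.8 to 21.2, 6.90 to 130 CPM).

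Macrophage markers were higher at D14 in 5 of 6 genes (median 1.09, 0.65 as a mean over cells), while the share of macrophage-like cells went from 0.525% to 0.607%. Dendritic cell markers were higher in 4 of 7 (median 1.10, 0.49 at a floor of 50 CPM), while the share of dendritic-like cells went from 0.240% to 0.835%. Glucocorticoid response genes were higher in 6 of 10 and lower in 1 (median 0.91), with TSC22D3, a textbook glucocorticoid target, at 180 and 486 CPM. DUSP1 and the chemokine receptor CXCR4 (561 to 1637 CPM) are members of this list and of others. Homing genes were higher in 4 of 7 (median 0.72), and selection response genes in 6 of 13 (median 0.32), such as NR4A3 (63.7 to 205 CPM), a nuclear receptor induced by T cell receptor signals. On the lower side, 4 of 5 extracellular matrix genes were lower (median -2.24, -1.05 with no floor, percentile 0). Type I collagen genes COL1A1 (63.0 to 4.53 CPM, ratio 0.0719, 0.0610 to 0.0843) and COL1A2 (52.8 to 4.20 CPM) stood out. They lead cluster 31, which held 0.400% of cells at E25 and 0.275% at D14. Oncofetal genes were lower in 4 of 8 (median -0.51, percentile 0.06). LIN28B, which blocks the maturation of let-7 microRNAs, was at 127 and 54.7 CPM, PLAG1, a growth-related transcription factor, at 74.5 and 36.6 CPM.

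Over all cells, B3GAT1, the enzyme that makes the CD57 sugar epitope, had the lowest ratio (95.5 to 2.60 CPM, 0.0272, 0.0219 to 0.0334). The neurexin family genes CNTNAP5 (212 to 41.6 CPM) and NRXN3 (1170 to 240 CPM) were lower too. Within double-positive-like cells, B3GAT1 (190 to 4.25 CPM) was lower as well, along with DPYSL3 (73.5 to 2.96 CPM), LRFN5 (90.3 to 11.1 CPM) and the splicing factor ESRP2 (130 to 16.8 CPM). STAT4 was 21.5-fold higher in this class (17.2 to 27.1, 9.03 to 194 CPM), PRTG, an immunoglobulin-superfamily receptor, 39.5-fold (23.2 to 73.1, 1.49 to 58.7 CPM) and PPP1R36 17.8-fold (13.7 to 23.5). HSPA2 was at 66.7 and 868 CPM there. IGLL1 was also higher there (2.76 to 50.6 CPM), far below its 280560 CPM in plasma-like cells, and whether this class expresses it is left open.

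Inside the double-positive-like class, 11 of 13 heat shock genes (median 1.51) and 6 of 9 immediate early genes (median 1.87, 1.09 with no floor) were higher at D14, both at percentile 100. Glucocorticoid response genes were higher in 5 of 8 and lower in 2 (median 1.65, 0.45 with no floor). Maturation and egress genes were higher in 6 of 11 (median 0.61) and antigen presentation genes in all 3 measured (median 1.58, 0.95 with no floor), B2M among them (27.0 to 145 CPM). DNTT, which adds nucleotides at receptor gene joints, was at 3999 and 7915 CPM, and ID3, an inhibitor of E proteins, at 61.2 and 398 CPM. Oncofetal genes were lower in 3 of 6 (median -0.67, -0.35 with no floor), with LIN28B at 94.6 and 15.5 CPM. Ribosomal protein genes were lower in 9 and higher in 2 of 64 (median -0.36).

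**Figure D2:**
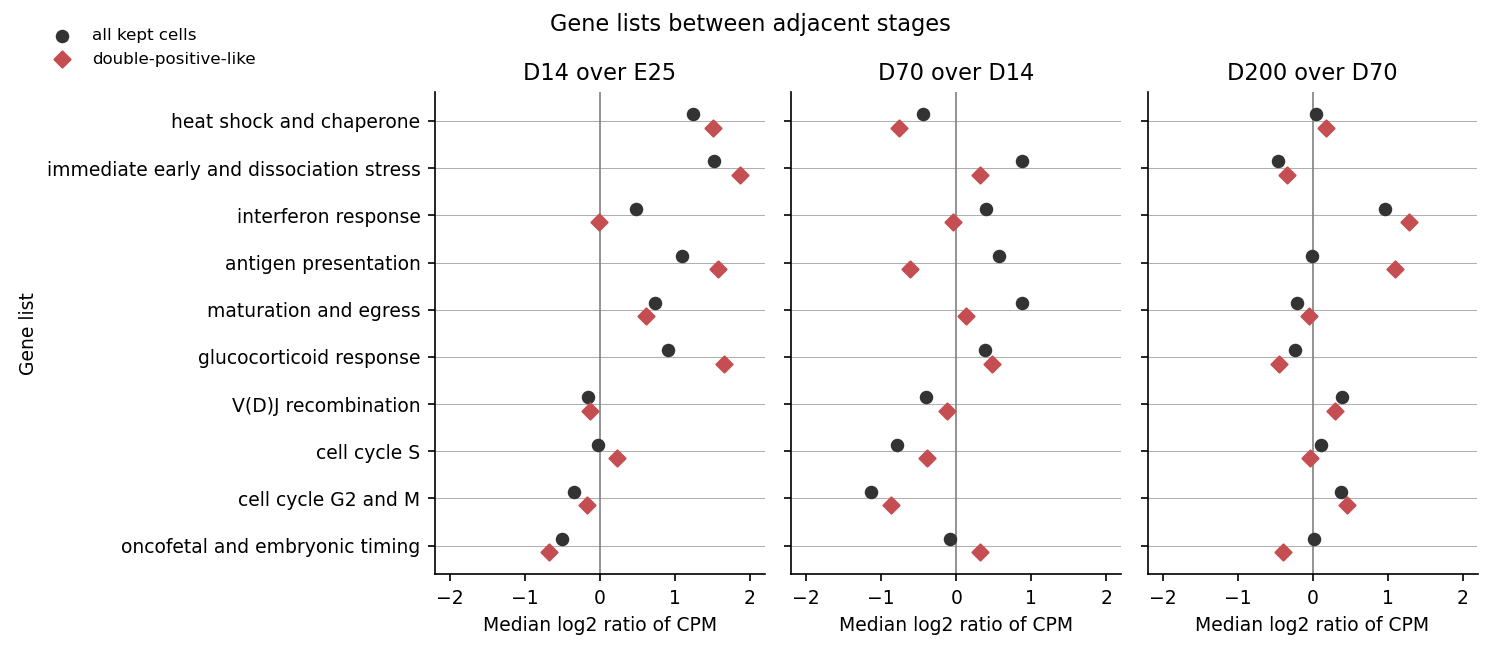
Median log2 ratio of CPM (x axis) of 10 gene lists (y axis) in the 3 comparisons of adjacent stages, over all kept cells (circles) and within double-positive-like cells (diamonds). The heat shock list stood at 1.23 and 1.51 at D14 over E25, the G2 and M list at -1.13 and -0.87 at D70 over D14, and the interferon list at 0.96 and 1.28 at D200 over D70.

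The comparison of D70 with D14 sets geese 70 days after hatching against geese 14 days after hatching. Cell division genes were lower at D70, while genes of mature T cells, of T cell selection and of B cells were higher. Of 31 genes of the G2 and M phases, 30 were at least 1.5-fold lower and 0 higher (median -1.13, percentile 0), and of 28 S phase genes 24 were lower (median -0.79, percentile 0). Cyclin A2 (CCNA2) was at 88.2 and 31.0 CPM, the mitotic activator CDC20 at 172 and 67.9 CPM, CDC45, a replication factor, at 42.6 and 14.0 CPM, and thymidine kinase TK1 at 183 and 63.0 CPM. CKS2, a subunit of cyclin-dependent kinases, had the lowest ratio (169 to 31.4 CPM, 0.186, 0.173 to 0.200), and PIMREG, a mitotic regulator, was at 78.8 and 25.8 CPM. Cycling-like cells held 21.7% of cells at D14 and 6.19% at D70.

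With each cell thinned to 1000 UMIs, the share of cells with at least 2 UMIs of the G2 and M list was 45.1% at D14 (44.0% to 46.1%) and 23.2% at D70 (22.2% to 24.1%), against 64.4% and 45.8% unthinned. The same share was 42.8% at E25 (41.7% to 43.8%) and 27.1% at D200 (26.1% to 28.1%), against 75.4% and 41.8% unthinned. Cells below 1000 UMIs, 177, 1372, 692 and 2043 from E25 to D200, were left out. In mature single-positive-like cells, the thinned share was 5.94% at D14, 5.07% at D70 and 4.76% at D200, at median depths of 3406.5, 2406 and 1720 UMIs. Clusters with cell cycle markers were named cycling-like, so lower shares in the mature single-positive-like and double-positive-like classes follow in part from the naming. SMC4, a condensin subunit, gave 65.0%, 74.8%, 84.1% and 81.1% of the list's UMIs in double-positive-like cells, so the share was also taken without it, a choice made after its level was seen. It was then 25.3% at E25, 26.9% at D14, 7.99% at D70 and 11.1% at D200 over all cells. In double-positive-like cells the share was 33.2%, 41.0%, 33.0% and 34.2% with SMC4, and 7.39%, 6.22%, 2.29% and 2.65% without it, where mature single-positive-like cells had 0.845% at D70 (0.341% to 1.73%). No order of E25 and D14 is read from these shares, since the list's CPM median was lower at D14 (-0.34 over all cells).

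**Figure D3:**
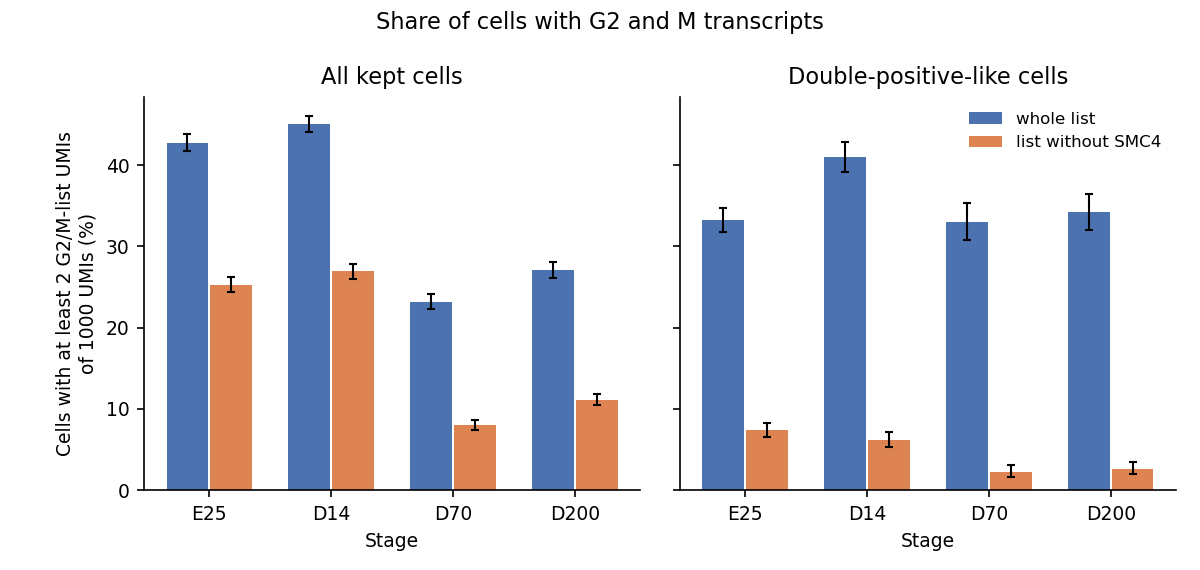
Share (%) of cells with at least 2 UMIs of the G2 and M list after thinning to 1000 UMIs, by stage (x axis), over all kept cells (left) and double-positive-like cells (right), with exact 95% binomial intervals. Over all cells it was 45.1% at D14 and 23.2% at D70 with the whole list, and 26.9% and 7.99% without SMC4.

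Of 15 maturation and egress genes, 10 were higher at D70 and 0 lower (median 0.88, percentile 100), among them KLF2 (98.9 to 303 CPM), the egress receptor S1PR1 (7.94 to 20.9 CPM), STAT4 (130 to 309 CPM) and CD40LG (24.1 to 51.6 CPM), a helper T cell ligand. Mature single-positive-like cells held 0.968% and 9.97% of cells at the same stages, and KLF2 leads their cluster. Selection response genes were higher in 9 of 15 (median 0.66, percentile 100), such as RUNX3, a CD8 lineage factor (29.5 to 88.0 CPM), and NFATC1 (63.3 to 149 CPM). Homing genes were higher in 6 of 10 (median 0.83), T cell receptor signalling genes in 5 of 22 (median 0.38), regulatory T cell genes in 3 of 9 with 1 lower (median 0.50), gamma-delta or innate-like genes in 5 of 7 (median 0.76) and cytotoxic genes in 3 of 4 (median 1.09, 0.48 with no floor). CTLA4, a brake on T cell activation, was at 54.5 and 157 CPM, and GZMM, a granzyme, at 10.9 and 24.1 CPM. Over all cells, immediate early genes were again higher in 9 of 12 (median 0.88), FOSB at 54.3 and 171 CPM. By contrast, 4 of 13 heat shock genes were lower (median -0.44). The immediate early median was 0.32 in double-positive-like cells, but -0.41 in their cluster 0 alone, with 1 of 9 higher and 3 lower. In cycling-like cells it was 0.17, with 0 of 10 higher. The other single classes and clusters measured had positive medians, from 0.13 in cluster 10 to 0.82 in cluster 8.

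B cell genes were higher in 6 of 7 (median 1.31, percentile 100), with EBF1 at 57.1 and 194 CPM and POU2AF1, a B cell co-activator, at 4.78 and 21.5 CPM. EYA1 (11.0 to 71.3 CPM, 6.47-fold, 5.80 to 7.24, log2 ratio 2.59 but 4.14 as a mean over cells) and CREB5 (24.7 to 96.6 CPM), which also lead the B-like cluster 14, were among the highest ratios. So were GPR171, a G protein-coupled receptor (41.3 to 251 CPM, 6.09-fold, 5.76 to 6.45), the poly(A) polymerase TENT5A (26.3 to 106 CPM), the GTPase MRAS (14.0 to 53.8 CPM) and IGLL1 (1785 to 6464 CPM). The 28 plasma-like cells of D70 held 83.9% of that library's IGLL1 UMIs, and as a mean over cells IGLL1 had a log2 ratio of 1.03 instead of 1.86. Antigen presentation genes were higher in 4 of 9 (median 0.56), with B2M at 399 and 832 CPM, but in double-positive-like cells 2 of 3 were lower and 0 higher (median -0.61, -0.03 with no floor). V(D)J recombination genes were lower in 4 of 9 (median -0.40, percentile 1.17), with RAG1 at 1010 and 566 CPM and RAG2 at 90.8 and 48.1 CPM. Oncofetal genes as a list stood at -0.08, with IGF2BP3, an RNA-binding protein of embryonic cells (153 to 30.1 CPM, ratio 0.197, 0.182 to 0.212), and LIN28B (54.7 to 15.6 CPM) lower and ARID3A (18.4 to 50.1 CPM) higher. The fatty acid carrier FABP7 (62.6 to 16.3 CPM) and the surface glycoprotein CD24 (965 to 314 CPM) were lower too.

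Within double-positive-like cells, 9 of 13 heat shock genes were lower at D70 (median -0.76, percentile 0), HSPA2 at 868 and 195 CPM and HSP90AA1 at 2434 and 948 CPM. G2 and M genes were lower in 6 of 9 (median -0.87), and selection response genes were higher in 3 of 9 (median 0.43), such as NFKBIA (115 to 245 CPM), an inhibitor of NF-kB. Glucocorticoid response genes were higher in 3 of 10 (median 0.48). IGF2BP3 was at 120 and 7.83 CPM (ratio 0.0655, 0.0425 to 0.0969), PRTG at 58.7 and 5.12, PPP1R36 at 115 and 12.6 and NPM3, a nucleolar chaperone, at 104 and 15.1 CPM. On the higher side, FABP3, a fatty acid carrier, was at 4.25 and 104 CPM (24.5-fold, 16.1 to 39.2), and DOK7, an adaptor protein, at 38.2 and 223 CPM. The ephrin receptor EPHA4 (15.7 to 74.7 CPM) and the pyridoxal kinase PDXK (18.5 to 74.7 CPM) followed. TDRD6, a tudor domain gene, had 4 UMIs at D14 and 203 at D70, a ratio of 82.7 with a counting interval of 31.8 to 307.

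The comparison of D200 with D70 sets geese 200 days after hatching against geese 70 days after hatching. Most interferon response genes were higher at D200. Some genes of receptor rearrangement were higher too, and minor parts of the immediate early, glucocorticoid response and regulatory T cell lists were lower. Of 16 interferon genes, 12 were at least 1.5-fold higher and 0 lower (median 0.96, percentile 100). USP18, which limits interferon signalling, was 4.15-fold higher (3.72 to 4.62, 17.1 to 71.0 CPM). RSAD2, an antiviral enzyme, was at 24.3 and 73.4 CPM, EPSTI1 at 21.1 and 62.5 CPM and CMPK2 at 14.2 and 41.8 CPM. DDX60, a helicase of antiviral signalling outside the list, was 5.92-fold higher (5.23 to 6.72, 12.0 to 71.2 CPM). Cluster 16, with RSAD2 and RNF213 among its leading genes, held 1.32% of cells at D70 and 6.24% at D200. It carried the single-positive markers CCR7, KLF2, IL7R, CD40LG and RUNX3 without reaching the naming rule. Mature single-positive-like cells held 9.97% and 3.07%, and with cluster 16 added 11.3% (10.6% to 12.0%) and 9.31% (8.73% to 9.92%). The unnamed cluster 5 carried the same 5 markers and held 6.57% and 8.30%, so the difference depends on which unnamed clusters are added.

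Of 9 V(D)J recombination genes, 4 were higher at D200 (median 0.39, percentile 99.6), with RAG1 at 566 and 1128 CPM and DNTT at 1331 and 2630 CPM. Notch and T lineage genes had a median of 0.47, with 2 of 14 higher and 1 lower, such as LEF1 (909 to 1509 CPM). CD8B was at 275 and 521 CPM. Cluster 0, which leads with DNTT and RAG1, held 10.1% of cells at D70 and 34.4% at D200, and ATRNL1 (121 to 573 CPM, 4.74-fold, 4.56 to 4.94) and LRFN2 (49.4 to 200 CPM) are among its leading genes. Cluster 4, also double-positive-like and with DNTT among its leading genes, went the other way, from 17.8% to 1.61%. No order of D70 and D200 is read from the share of the whole class. G2 and M genes had a median of 0.38, with 3 of 28 higher, but the order of D70 and D200 in the share of cells with G2 and M transcripts differed with and without thinning. ZBTB20, a transcriptional repressor, had the highest ratio (8.60-fold, 7.67 to 9.68) and stood at 112 CPM at D200. PPP1R36 was at 49.3 and 220 CPM.

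Immediate early genes were lower in 4 of 12 at D200 (median -0.46, percentile 0), FOSB at 171 and 69.9 CPM and ATF3 at 71.5 and 35.6 CPM. Glucocorticoid response genes were lower in 2 of 10 (median -0.23). Their member FKBP5, a co-chaperone of the glucocorticoid receptor, had the lowest ratio among the genes named over all kept cells at D200 over D70 (80.4 to 17.6 CPM, 0.219, 0.195 to 0.245). Regulatory T cell genes were lower in 3 of 9 (median -0.13), CTLA4 at 157 and 65.4 CPM and IL2RA at 53.9 and 23.7 CPM, and B cell genes in 2 of 7 (median -0.32). Lipid storage genes were lower in 2 of 4 (median -0.69, -0.22 with no floor), among them the droplet coat gene PLIN2 (124 to 69.7 CPM). GPR171 (251 to 69.0 CPM), FSTL4 (71.5 to 16.8 CPM), the kinase-dead ephrin receptor EPHB6 (78.3 to 21.9 CPM), galectin LGALS1 (228 to 69.0 CPM) and the RNA-degrading regulator ZC3H12D (423 to 147 CPM) were lower as well. GPR171 and ZC3H12D lead the mature single-positive-like cluster. GPR171 was also lower inside each class and cluster in which it was followed, such as double-positive-like (25.3 to 2.62 CPM) and B-like cells (106 to 33.0 CPM).

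Within double-positive-like cells, 11 of 14 interferon genes were higher at D200 and 0 lower (median 1.28, percentile 100). USP18 was at 7.83 and 73.8 CPM (9.43-fold, 6.31 to 14.7), SAMD9L, an antiviral factor, at 7.23 and 73.6 CPM (10.2-fold, 6.72 to 16.1), and RSAD2 at 4.22 and 38.3 CPM. Without cluster 26, an interferon-high part of the class with 218 of its 3597 cells at D200, 6 of 9 were higher (median 0.85), a setting added after the data were seen. Antigen presentation genes were higher in 3 of 5 (median 1.10, 0.32 at a floor of 50 CPM), with B2M at 160 and 403 CPM and NLRC5, an activator of MHC class I genes, at 18.1 and 48.4 CPM. ZBTB20 was at 14.2 and 234 CPM (16.5-fold, 12.3 to 22.6), PRTG at 5.12 and 135 CPM (26.4-fold, 16.3 to 45.6) and the amino acid sensor CASTOR2 at 8.73 and 69.8 CPM. Glucocorticoid response genes were lower in 5 of 10 (median -0.45) and immediate early genes in 4 of 10, with 1 higher (median -0.34). The class lay mostly in cluster 4 at D70, and in cluster 0 alone the immediate early median was 0.20, with 1 of 8 higher and 1 lower, and the glucocorticoid median -0.57. STAT4 was at 465 and 128 CPM, the amino acid transporter SLC7A5 at 372 and 51.2 CPM, FSTL4 at 119 and 16.7 CPM and SH3BGRL2 at 62.9 and 9.29 CPM. TDRD6 (61.1 to 1.19 CPM) and FABP3 (104 to 4.53 CPM), both higher at D70 than at D14, were lower again.

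**Figure D4:**
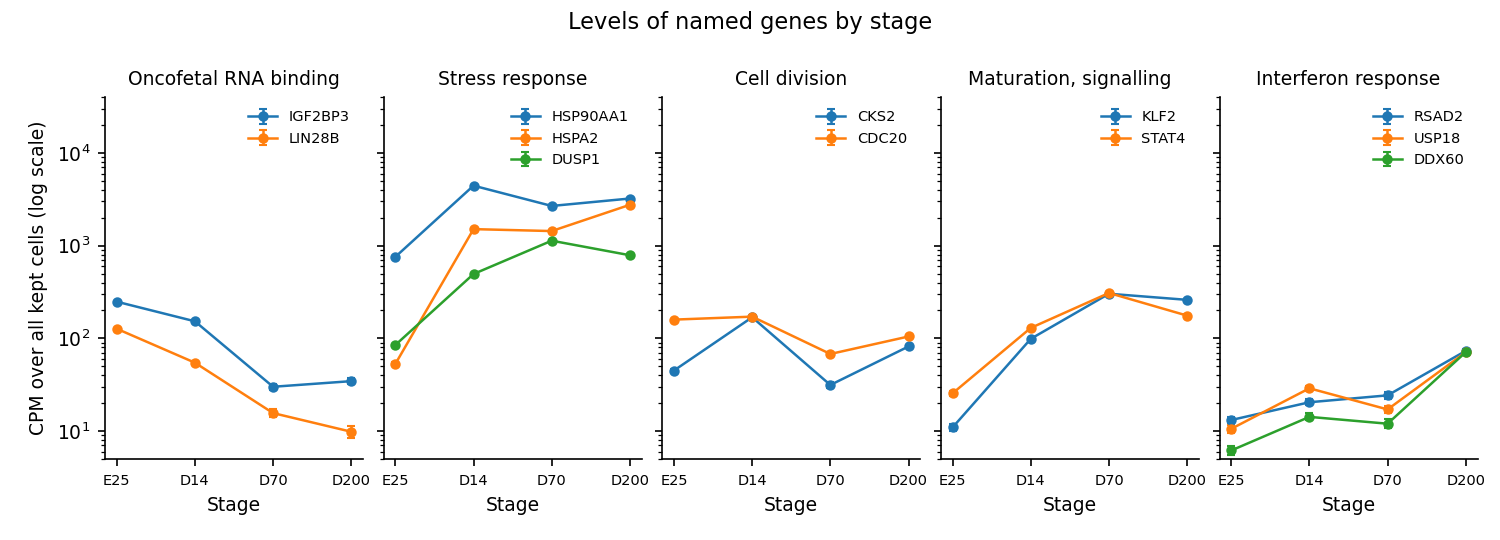
CPM over all kept cells (log scale) of 12 genes by stage, 1 pooled library each, with exact 95% Poisson intervals that are mostly smaller than the points. HSP90AA1 went from 758 to 4445 CPM between E25 and D14, CDC20 from 172 to 67.9 CPM between D14 and D70, and USP18 from 17.1 to 71.0 CPM between D70 and D200.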

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

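All alternatives were fixed before the data were examined except 3: the G2 and M list without SMC4, mature and non-T classes left out, and cluster 26 left out, which were chosen after the data were seen. Of 462 gene values under alternatives, 339 stayed within the counting interval, 123 moved and 0 reversed, and of 372 list values 285 stayed, 87 moved and 0 reversed. The counts of 11 heat shock genes at D14 (all cells, 11 to 14 over the alternatives, and double-positive-like, 11 to 12), 30 G2 and M genes at D70 (21 to 30) and 12 interferon genes at D200 (9 to 13) stayed within 1.5 times, and their medians ranged from 1.17 to 1.30, 1.16 to 1.52, -1.41 to -1.07 and 0.88 to 1.08. The 11 of 14 interferon genes in double-positive-like cells became 6 of 9 at a floor of 50 CPM and 6 of 9 with cluster 26 left out, where fewer genes reached the floor. Over the same 14 members without cluster 26, 9 were higher. Other medians moved by over 1.5 times. Over all cells with no floor, they became -1.05 for extracellular matrix (main -2.24), 0.24 for early thymic progenitor (1.17) and 0.31 for lipid storage genes (0.61) at D14, 0.48 for cytotoxic (1.09) and 0.50 for early thymic progenitor genes (0.91) at D70, and -0.22 for lipid storage genes (-0.69) at D200. At a floor of 50 CPM they became 0.49 for dendritic cell markers (1.10) at D14 and 0.49 for homing genes (0.83) at D70, and as a mean over cells 0.65 for macrophage markers (1.09) at D14. In double-positive-like cells with no floor, they became 1.09 for immediate early (1.87), 0.95 for antigen presentation (1.58), 0.45 for glucocorticoid response (1.65) and -0.35 for oncofetal genes (-0.67) at D14, and -0.03 for antigen presentation (-0.61) at D70. Early thymic progenitor genes there at D14 (0.79) had 0.02 with no floor and 1.81 at a floor of 50 CPM. Lipid storage genes there at D200 (-1.29) had -0.35 with no floor. Antigen presentation there at D200 (1.10) was 0.32 at a floor of 50 CPM. Among genes, EYA1 at D70 over D14 had a log2 ratio of 4.14 as a mean over cells (2.59) and IGLL1 1.03 (1.86). The median ratio of all genes lay between -0.08 and 0.06 under every scaling.

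Shares of cells moved more, and the cause was not tested. The double-positive-like difference D200 minus D70 (10.4 points) was 12.6 at 300 genes, 11.9 with no mitochondrial limit and -0.437 at 800 genes, where its direction reversed. D14 minus E25 (-10.6) ranged from -23.8 at 800 genes to -9.99 at 300 genes, and D70 minus D14 (-9.35) from -9.47 to -5.75, the latter at 800 genes. The cycling-like difference D14 minus E25 (5.45) reversed at resolution 0.5 (-0.833) and with 3000 variable genes (-3.67). D70 minus D14 (-15.6) was -12.5 with no mitochondrial limit, -17.2 with no doublet removal, -14.2 at resolution 0.5, -11.9 with 3000 variable genes and -11.5 on library-centred values. The B-like difference D14 minus E25 (2.37) was 3.08 at 800 genes. The mature single-positive-like difference D70 minus D14 (9.97% less 0.968%) was 12.2 at 800 genes, 10.2 with no mitochondrial limit, 9.93 with no doublet removal, 14.6 at resolution 0.5, 9.96 at resolution 1.5 and 9.89 on library-centred values. D200 minus D70 (-6.89) ranged from -9.03 to -4.95. At resolution 0.5 the regulatory T-like differences reversed, to -1.41 (D70 minus D14) and 0.0496 (D200 minus D70).

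The share of cells with G2 and M transcripts over all cells, D14 minus E25 (2.30), reversed when thinned to 2000 UMIs (-2.82), with at least 1 UMI (-1.14) and not thinned (-11.0). D70 minus D14 (-21.9) was -23.4 with no doublet removal, -26.6 thinned to 2000 UMIs, -19.5 with at least 1 UMI, -18.5 not thinned, -18.9 without SMC4 and -19.2 with mature and non-T classes left out. D200 minus D70 (3.89) reversed to -4.06 when not thinned. In double-positive-like cells, D14 minus E25 (7.74) reversed when not thinned (-12.3) and without SMC4 (-1.17). Depth limits these shares, as thinning leaves out cells below 1000 UMIs. No paired analysis was possible because each stage has 1 library, and leaving out a library would leave its stage with none.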

Other observations

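The oncofetal genes IGF2BP3 and LIN28B, picked with the other genes of this paragraph after their values were seen, were followed by class. IGF2BP3 stood at 160, 120, 7.83 and 2.86 CPM in double-positive-like cells, from E25 to D200, and at 318 CPM at E25 and 21.6 CPM at D200 in cycling-like cells. LIN28B stood at 94.6, 15.5, 2.41 and 1.43 CPM in the former and at 131, 44.4, 9.82 and 5.88 CPM in the latter. From D70 to D200, IGF2BP3 was higher in B-like cells (43.5 to 80.8 CPM) and over all cells (30.1 to 34.6 CPM). Cycling-like cells lay in other clusters at other stages, at E25 mostly in clusters 17 and 25 (8.64% and 3.94% of kept cells), at D14 mostly in clusters 11, 18 and 21 (7.19%, 4.23% and 4.18%). HSPA2 and its neighbour PPP1R36 were both higher at D14 than at E25, lower at D70 and higher again at D200 inside each class and cluster in which they were followed. At E25, B-like cells (25 cells, with 8 HSPA2 UMIs and 1 PPP1R36 UMI) and cluster 2 (172 cells) were below the minimum of 200 cells. Over all kept cells, HSPA2 differed little between D14 and D70 (1510 and 1439 CPM). In cycling-like cells, HSPA2 stood at 26.3, 1278, 707 and 1745 CPM and PPP1R36 at 4.49, 134, 40.4 and 204 CPM. In double-positive-like cells they stood at 66.7, 868, 195 and 1107 CPM and at 6.48, 115, 12.6 and 88.1 CPM. ZBTB20 was at 85.1, 41.4, 14.2 and 234 CPM in double-positive-like cells.

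The remaining lists had medians on both sides of 0. At D14 over E25, medians were 0.49 for interferon response (5 of 11 higher), 1.17 for early thymic progenitor genes (0.24 with no floor, 4 of 6 higher, IGLL1 and the B cell gene MEF2C among them), 0.34 for gamma-delta or innate-like genes (3 of 6 higher, 1 lower), 0.29 for regulatory T cell genes (1 of 8 higher, 1 lower) and 0.61 for lipid storage genes (2 of 3 higher). They were -0.15 for V(D)J recombination, -0.13 for Notch and T lineage genes, -0.02 for T cell receptor signalling, -0.06 for apoptosis, 0.03 for glycolysis, 0.02 for sex steroid receptors and targets, 0.11 for the nuclear-encoded respiratory chain, -0.12 for ribosomal proteins and -0.32 for the mitochondrial genome (0 of 13 higher, 3 lower). At D70 over D14, medians were 0.40 for interferon response (3 of 14 higher, 1 lower), 0.91 for early thymic progenitor genes (5 of 7 higher), 0.38 for glucocorticoid response (4 of 10 higher), -0.29 for macrophage markers (2 of 6 lower) and 0.35 for dendritic cell markers (2 of 7 higher, 1 lower). At D200 over D70, they were -0.23 for selection response (1 of 15 higher, 3 lower), -0.21 for maturation and egress (2 of 15 lower), -0.29 for homing (2 of 10 lower), -0.35 for gamma-delta or innate-like genes (3 of 7 lower), -0.26 for glycolysis and 0.04 for heat shock (1 of 13 higher). At D70 over D14, the nuclear-encoded respiratory chain had -0.34 and the mitochondrial genome 0.37, and at D200 over D70 they had -0.11 and -0.04. Endothelial and erythroid lists had 0 members at 20 CPM or more over all cells in any comparison, and cytotoxic genes had 1 at D14 over E25. Thymic stroma signals had 1 in each comparison, and thrombocyte and thymic epithelial lists 0 or 1, so no median is given for these.

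The tests of the 3 patterns below were all chosen after the results they measure had been seen. The test of a like interferon amount in every class was rewritten, since its first form took only classes that favoured that explanation. A first, looser test of the amount of IGLL1 per droplet, which favoured free RNA, was replaced by the pair given here.

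IGLL1 was found in 6.76% of double-positive-like cells at D14, 18.8% at D70 and 14.8% at D200, and in 22.7%, 46.0% and 43.9% of cycling-like cells. Free RNA in a like amount in every droplet is argued against, since 6 of 9 shares of other T classes lay apart from the double-positive-like share. For free RNA in the mix of the captured plasma-like cells, their IGLL1 to JCHAIN ratio was set against the double-positive-like ratio. It was 2.10 times higher at D14 (1.51 to 2.88), 1.77 times at D70 (1.31 to 2.34) and 1.40 times at D200 (0.990 to 1.92), with 1 excluded in 2 of 3 libraries. These intervals leave out the spread among the 27, 28 and 30 plasma-like cells, so they cannot decide and this explanation stays open. Free RNA in proportion to the UMIs of a droplet stays open, as 1 of 9 shares lay apart at 1000 UMIs per cell, in cycling-like cells at D70 (6.73% against 13.4%). So does free RNA of 1 source, as 0 of 9 quotients of that ratio excluded 1 but counts were as low as 3 UMIs, and expression in these cells was not tested.

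Heat shock and chaperone genes were higher at D14 than at E25 over all cells. As single classes or clusters, only double-positive-like cells, cycling-like cells and cluster 10 had 200 cells in both libraries. Their medians were 1.51, 1.17 and 1.03 (log2). Both classes lay in different clusters at E25 and D14, so only cluster 10 (273 and 368 cells) held the cluster fixed. Within cluster 10, another makeup of cell classes is argued against as the whole cause. For the other cells this comparison cannot decide, since their clusters differed between the libraries or were too small. A response to handling before lysis predicts that immediate early genes are higher in every class as well, and their lowest median was 0.886 in a single class or cluster (cluster 10) and 0.87 in the other T clusters with cluster 16 as 1 group. In the classes and clusters measured, that is what handling would give, but a stage effect that reaches every class would give it too. The 2 therefore cannot be told apart with 1 library per stage. The stage itself, including hatching, stays open and was not tested.

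Interferon genes were higher at D200 than at D70 within double-positive-like cells (median 1.28). Cluster 26 alone is argued against as the cause, since the same 14 members had a median of 0.784 without it, with 9 at least 1.5-fold higher. A change of every cell class by a like amount could be neither excluded nor shown. B-like cells had 1.07, cycling-like cells 1.04 and the other T clusters with cluster 16 had 0.95, but the lowest median inside a class or cluster was 0.292, in mature single-positive-like cells. The unnamed clusters 5, 6, 2 and 8 had 0.45, 0.57, 0.72 and 0.80, and the unnamed clusters 10 and 3 had 1.00 and 1.75. With cluster 16, which went from 1.32% to 6.24% of cells, mature single-positive-like cells had 1.47, and -0.78 at D70 over D14. Whether interferon genes shaped the clusters was not tested, as no clustering without them was run. Age, an infection of 1 or more of the pooled birds and the library stay open and were not tested.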
